A study of Sus scrofa with 24 samples.

How the data were processed

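The 24 samples came from 4 tissues of 6 pigs. Per the labels, 200 ng of RNA with an integrity number over 7.5 was labelled with Cy3 and hybridised to a one-colour Agilent array with 1 array per sample and no pooling. The replicate numbers of the labels are animal numbers, so they pair the samples of the 4 tissues. The pairing was checked on deviations from the tissue means, where the 36 pairs of arrays from the same animal had a mean r of 0.17, with 26 over 0.1 and the lowest at -0.021, against a mean of -0.034 for the 180 pairs from different animals.

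The deposited scanner files hold signals as intensity, computed by Agilent Feature Extraction 10.10.1.1, which subtracted the background and removed the spatial trend within each array. These signals are not normalized between arrays. The deposited table of the authors holds log2 values for 44600 probes. In that table the sorted values of the 24 columns are identical and every column has a median of 8.24, as quantile normalization between arrays gives. The authors name limma for this step, and its version is not given in the sources used here. The scale and direction of the authors' values were checked against the scanner signals, and their differences between tissues on shared slides followed those of the scanner (r = 0.987 for Peyer minus Jejunum and 0.997 for Spleen minus Liver). For tissues on different slides r was 0.362 for Peyer minus Spleen, 0.738 for Jejunum minus Liver, 0.73 for Peyer minus Liver and 0.595 for Spleen minus Jejunum. How the table was centred is not given in the sources used here. The scanner signals were therefore used for all results, and the authors' values entered as an alternative.

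The arrays lie on 6 slides. Slides 1, 2 and 3 hold Liver and Spleen of animals 68 and 69, 70 and 71, and 73 and 75, and slides 4, 5 and 6 hold Jejunum and Peyer of the same pairs of animals. Slide 6 was scanned on another day than the others. Spleen with Liver and Peyer with Jejunum can be compared within slides, and the other 4 comparisons are confounded with the slide set.

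Of 61625 spots 1319 were controls. The other 60306 gave 60305 probes, since 1 probe was spotted more than once and was averaged. Signals were taken as log2, and the 75th percentile of each array was subtracted. A probe was kept where the scanner software called it well above background on all 6 arrays of at least 1 tissue and called no outlier for it (136 probes had such a call), which left 42650 probes. No probe was saturated on any array, and 31584 were well above background on all 24. Gene names came from the symbol in the file for 15283 probes, an accession for 7606, a gene number for 2370, the name in the file alone for 1368, a synonym for 196 and a description for 54, and 33428 probes stayed unnamed. Of the tested probes 53.3% were named (44.6% of all probes), which gave 10910 genes. A gene with several probes is represented by the probe with the highest mean over the 24 arrays. Among 5379 genes with several probes, probes were called in opposite directions in 4 between Peyer and Jejunum, 37 between Spleen and Liver, 22 between Peyer and Spleen and 31 between Jejunum and Liver.

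Comparisons were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the 24 arrays with tissue as the only term, which left 20 residual degrees of freedom and a prior of 2.97. P-values were adjusted by Benjamini and Hochberg over the probes of each comparison, and a gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. A gene was called enriched in a tissue at an adjusted p under 0.05 and a log2 difference of at least 2 over each of the other 3 tissues. The animal effect is the F-test of animal beside tissue. Where a gene was not well above background on any array of a tissue, its fold is a lower bound, taken against the lowest signal that was well above background on each array of that tissue, or the gene's own signal where that was higher, and is written as at least that fold. Of the 615 genes enriched in Liver, 26 were well above background on no array of the other 3 tissues.

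A total of 35 gene lists, written with their own comparison before the data were examined, were tested with limma camera at a preset correlation between genes of 0.01, adjusted over 210 tests. They were tested again with an estimated correlation and with fry. The tests, the thresholds, the lists, the alternatives listed below and the rule for naming genes were chosen before the data were examined.

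Named genes follow that rule. In Peyer minus Jejunum, Spleen minus Liver, Peyer minus Spleen and Jejunum minus Liver they are the 5 highest and 5 lowest differences among called genes with 1 name that were well above background on all 12 arrays and differed in the same direction in 6 animals, and up to 3 members of each list with the largest absolute difference, called or not. To these come 5 enriched genes per tissue with the largest smallest difference among those well above background on all 24 arrays, the 5 genes with the highest F of the animal term, the detected sex-linked genes, and up to 3 members of any list that passed in Peyer minus Liver or Spleen minus Jejunum and not in its own comparison. Names of clones or accessions were passed over, and a named gene may be given in another comparison. Some genes selected by the rule are not reported here, and others were not named in their place.

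Profile correlations are Pearson r across the 42650 probes between tissues of the same animal, compared by exact sign-flip permutation over 6 animals. Sharing of deviations between tissues was set against all 720 pairings of animals and the 8 that stay within slides. The alternatives were median centring, quantile normalization, normexp background correction with an offset of 50 and quantile normalization, the authors' values, no filter, only probes well above background on all arrays, the mean of all probes of a gene, a trended prior, array weights, only the 12 arrays compared, adjusted p alone, limma treat, the animal as a block, slide as a fixed block on the 12 arrays compared or as a random block, each slide alone, each animal left out and, for the animal effect, each tissue left out. Leaving out the Peyer array of animal 71, the Spleen arrays of animals 68, 71 and 75, the Spleen array of animal 73, or slide 6 was chosen after the data were seen.

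The procedure was tested on simulated, independent genes with planted differences. Between Peyer and Jejunum 89% of 100 genes planted at a log2 of 1.5 and 99% of 100 planted at 3 were recovered, with 0 of 10710 unchanged genes called by limma, and between Spleen and Liver 0 of 10910 were called. Of 50 genes planted as enriched in Peyer 0% were recovered at 1.5, below the threshold, and 100% at 3. A planted list was recovered with 0 of 204 other tests passing, 93.5% of 200 planted animal effects were recovered with 6 of 10710 unchanged genes called, and sharing was found in 4 of 6 tissue pairs when planted and in 0 when not. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures, and the R package data.table, version 1.17.8, was used.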

Results

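Gene expression was measured in 4 tissues of 6 crossbred pigs (Sus scrofa) aged 10 weeks that had been weaned on day 28. The tissues were liver, spleen, a stretch of jejunum without Peyer's patches, here called Jejunum, and a stretch of jejunum holding a Peyer's patch, here called Peyer. A Peyer's patch is an aggregate of B cell follicles in the wall of the small intestine, covered by a specialised epithelium. Each of the 6 animals, numbered 68, 69, 70, 71, 73 and 75 in the labels, gave 1 sample of each tissue, for 24 one-colour arrays and n = 6 per tissue. The 75th percentile of the probe signal lay between 423.8 and 525.7 on the Liver arrays, between 275.4 and 1098.1 on Spleen, between 680.9 and 1001.3 on Jejunum and between 876.7 and 2261.9 on Peyer. Between 60.4% and 75.6% of the probes were well above background on an array, and the number of arrays limits the precision of every value. Levels are log2 signals relative to the 75th percentile of their own array, differences are on the log2 scale with the SE of the limma fit, and 10910 named genes were tested. A gene named with a difference between tissues differed in the same direction in 6 of 6 animals unless another number is given. A difference from a tissue where the gene was well above background on few arrays rests on signals near the background there.

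The tissues separated from each other before any test. The leading component held 51.7% of the variance, the next 30.8% and the third 5.9%. Array pairs of the same tissue correlated across probes at a mean r of 0.98 in Liver, 0.974 in Spleen, 0.986 in Jejunum and 0.971 in Peyer. For 22 of the 24 arrays the nearest other array was of the same tissue. The exceptions were the Peyer and Jejunum arrays of animal 71, which correlated with each other at 0.992, the highest value among the 276 pairs. Genes of hepatocyte plasma proteins averaged 7.6 ± 0.11 (SD, n = 6) in Liver and B cell genes 1.16 ± 1.04 in Peyer, 0.91 ± 0.2 in Spleen, -2.6 ± 0.13 in Jejunum and -3.13 ± 0.15 in Liver.

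**Figure D1:**
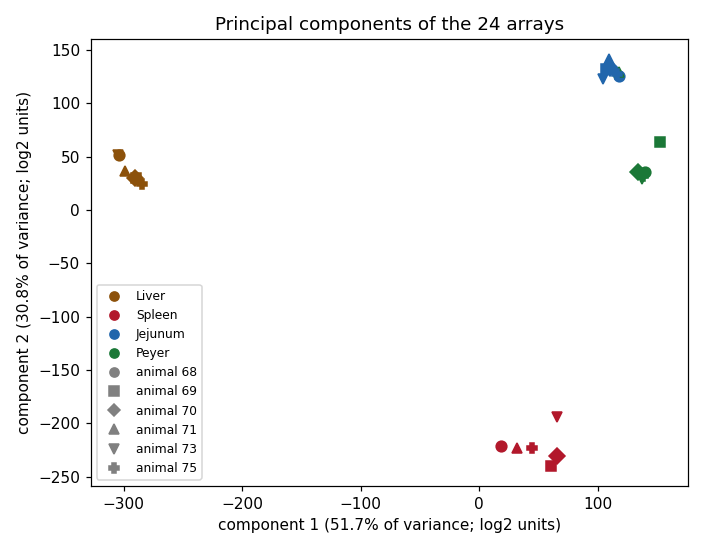
Scores of the 24 arrays on the leading principal components of the filtered probes, each point being 1 array and each colour 1 tissue, with the percent of variance on the axes (51.7% and 30.8%). Liver, Spleen and the intestinal arrays form separate groups, and the Peyer array of animal 71 lies beside the Jejunum arrays.

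**Figure D2:**
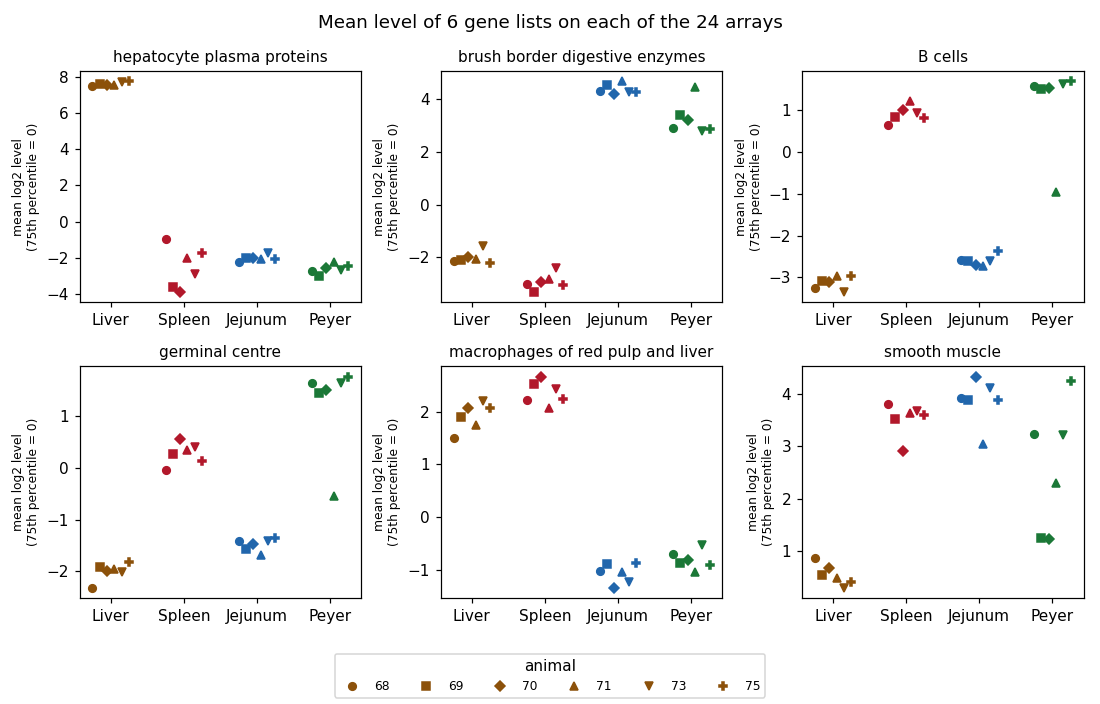
Mean log2 level, relative to the array's 75th percentile, of 6 fixed gene lists on each of the 24 arrays, with 1 point per animal in each tissue. B cell genes lie at -0.95 on the Peyer array of animal 71.

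Between Peyer and Jejunum, B cell genes were the most raised group. CR2, a complement receptor of B cells and follicular dendritic cells, was higher in Peyer by 8.12 ± 0.63 (SE, n = 6, limma adjusted p = 1.5e-08), and it was well above background on 1 of the 6 Jejunum arrays. MS4A1, which encodes the B cell surface protein CD20, was higher by 7.1 ± 0.44, FCRLA by 6.04 ± 0.49 and CD79B, a signalling chain of the B cell receptor, by 5.79 ± 0.47.

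Of the 17 measured B cell genes, 14 were higher in Peyer, 0 were lower and 3 were not called. Adjusted over the list alone, 14 were called as well, and this number of called genes follows the counts of a list in its own comparison. The list had a median of 3.68 and passed the limma camera test (adjusted p = 2.4e-16), but not with an estimated correlation (adjusted p = 0.067). The mean level of these genes was -0.95 on the Peyer array of animal 71 and between 1.51 and 1.69 on the other Peyer arrays. Within slides the median was 3.85 on slide 4, 2.95 on slide 5, which holds animals 70 and 71, and 4.02 on slide 6, and the list passed with slide as a block (adjusted p = 2.2e-12).

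Genes of the germinal centre, where B cells mutate and switch their antibody genes, were higher as well. ELL3, a transcription elongation factor, was higher by 7.01 ± 0.43 (adjusted p = 4.2e-10). The B cell chemokine CXCL13 was higher by 5.61 ± 0.76 and the transcriptional repressor BACH2 by 5.58 ± 0.45. Of 13 measured members 8 were higher, 0 lower and 5 not called, with 8 adjusted over the list alone. The median of 2.9 passed the test (adjusted p = 1e-08, and 0.1 with an estimated correlation). The Peyer array of animal 71 had a mean level of -0.54 for this list, against 1.44 to 1.75 on the others. Slide medians were 3.08, 2.02 and 3.11 (adjusted p = 6.4e-07 with slide as a block).

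Cell cycle genes moved with them. Of 23 measured members 14 were higher in Peyer, 0 lower and 9 not called, and 14 adjusted over the list alone. The median was 1.14 (adjusted p = 3.2e-05, and 0.49 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, was higher by 1.97 ± 0.44, the spindle factor TPX2 by 1.74 ± 0.41 and the replication helicase subunit MCM3 by 1.65 ± 0.35. This list too was low on the Peyer array of animal 71, at -0.55 against 0.8 to 1.1 on the others. Its slide medians were 1.53, 0.63 and 1.19 (adjusted p = 1.6e-06 with slide as a block).

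GP2, an uptake receptor of M cells in the epithelium over the follicles, was higher in Peyer by 6.65 ± 0.68 (adjusted p = 6.3e-07). PGLYRP1, a peptidoglycan recognition protein, was higher by 2.8 ± 0.66 in 5 of 6 animals, and the chemokine receptor CCR6 by 2 ± 0.42. Both were well above background on 1 of 6 Jejunum arrays, and with normexp they stood below 2-fold (0.95 and 0.69). In the list of follicle-associated epithelium and M cells 4 of 9 members were higher, 0 lower and 5 not called, with 4 adjusted over the list alone. Its median of 0.51 reached adjusted p = 0.048, and 0.26 with an estimated correlation, 0.1 with the 12 arrays compared alone and 0.071 with slide as a block on them, and slide medians of 0.4, 0.59 and 0.86. The call was also lost without animal 68 (adjusted p = 0.053), 69 (0.052) or 70 (0.069), and with median centring (0.097), quantile normalization (0.073) and normexp (0.082). The mean level was -0.52 on the Peyer array of animal 71 and 0.71 to 1.38 on the others.

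Among cytokines, LTB, which encodes lymphotoxin beta, was higher by 4.43 ± 0.45, IL6 by 3.1 ± 0.41 (well above background on 1 of 6 Jejunum arrays) and IL16 by 1.73 ± 0.24. Of 20 members 5 were higher, 0 lower and 15 not called, with 5 adjusted over the list alone and a median of 0.44, or 0.28 without animal 70 (adjusted p = 0.0021, and 0.22 with an estimated correlation). Slide medians were 0.22, 0.46 and 0.71 (adjusted p = 0.0045 with slide as a block). Toll-like receptors, which sense microbial products, gave 7 higher, 0 lower and 12 not called of 19, and 7 adjusted over the list alone. Their median was 0.21 (adjusted p = 0.027, and 0.27 with an estimated correlation), 0.09 without animal 70 and 0.38 without animal 71. TLR10 was higher by 2.38 ± 0.3, TLR2 by 2.08 ± 0.3 and TLR1 by 1.64 ± 0.2. The median of this list was -0.02 on slide 4, 0.6 on slide 5 and 1.03 on slide 6 (adjusted p = 0.028 with slide as a block).

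**Figure D3:**
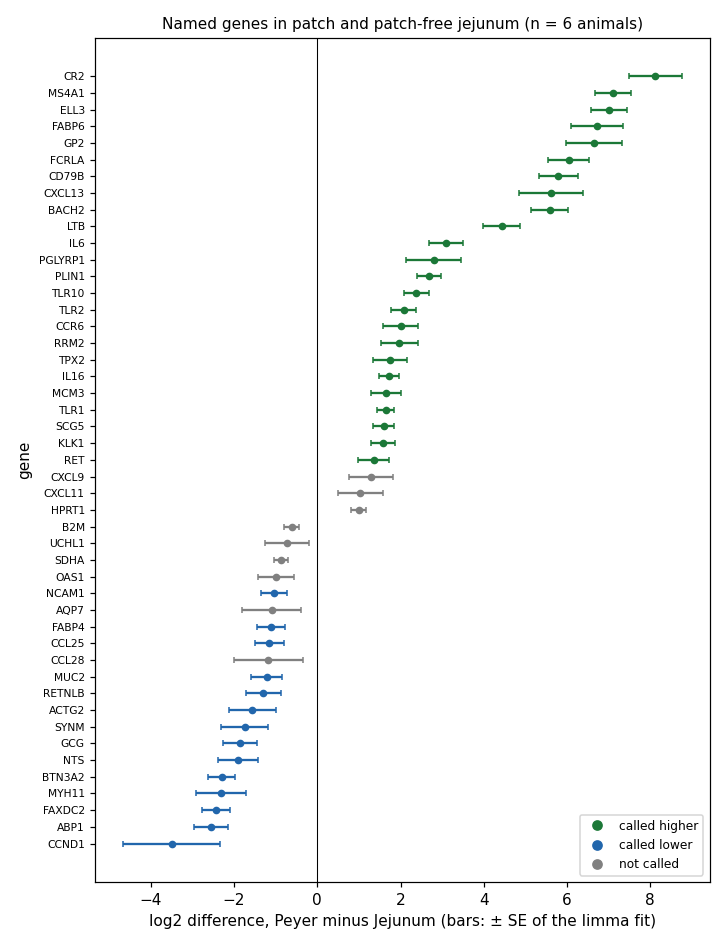
Log2 difference Peyer minus Jejunum of named genes of the fixed lists, with bars of ± 1 SE from the limma fit (n = 6 animals per tissue). CR2 lies highest at 8.12, and smooth muscle genes such as MYH11, at -2.32, lie to the left of 0.

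FABP6, a bile acid binding protein of the distal small intestine, was higher in Peyer by 6.72 ± 0.63 (adjusted p = 2.6e-07). Its slide differences were 7.48, 5.81 and 6.87 on slides 4, 5 and 6. Those of CR2 were 9.57, 5.83 and 8.95, those of ELL3 7.74, 5.68 and 7.62, and those of GP2 7.99, 4.77 and 7.19.

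Smooth muscle genes were lower in Peyer. MYH11, the smooth muscle myosin heavy chain, was lower at -2.32 ± 0.6 (adjusted p = 0.0043). The intermediate filament gene SYNM differed by -1.75 ± 0.57 and the enteric actin ACTG2 by -1.56 ± 0.56, each in 5 of 6 animals. Of 16 measured members 11 were lower, 0 higher and 5 not called, with 11 adjusted over the list alone. The median of -1.38 passed the test (adjusted p = 0.00067, and 0.49 with an estimated correlation). Without animal 70 the median was -0.9. Slides 4 and 5 gave medians of -1.68 and -2.08, and slide 6 gave -0.14 (adjusted p = 0.57), while the list passed with slide as a block (adjusted p = 0.0032). On slide 6 alone SYNM stood at 0.08. With the 12 arrays compared alone the calls of SYNM (adjusted p = 0.079) and ACTG2 (adjusted p = 0.066) were lost, and with slide as a block on them that of SYNM (adjusted p = 0.056). Both calls were also lost without animal 69 (-1.28 and -1.19), without animal 70 (-1.21 and -1.1) and with array weights (-1.06 and -0.89). ACTG2 also lost it with quantile normalization (-1.4, adjusted p = 0.068) and normexp (-1.42, adjusted p = 0.056).

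Other genes with the lowest differences were ABP1, which encodes diamine oxidase, at -2.55 ± 0.41, the fatty acid hydroxylase family gene FAXDC2 at -2.44 ± 0.34 and the butyrophilin gene BTN3A2 at -2.3 ± 0.33 (adjusted p = 2.6e-05). CCND1, which encodes cyclin D1, differed by -3.5 ± 1.16 (adjusted p = 0.019). Its level in Peyer was -5.71 in animal 69 and 2.39 to 5.14 in the others, its slide differences were -6.42, -0.85 and -3.25, it differed by -1.85 without animal 69, and the call was lost with the 12 arrays compared alone (adjusted p = 0.078, and 0.077 with slide as a block on them), without animal 73 (-3.55, adjusted p = 0.056) and without animal 75 (-3.56, adjusted p = 0.055).

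The secretory and neural lists did not pass. Of 15 goblet and Paneth cell genes 1 was higher, 2 lower and 12 not called, with 3 adjusted over the list alone and a median of -0.46 (adjusted p = 0.64). The kallikrein KLK1 was higher by 1.58 ± 0.28, the goblet cell product RETNLB was lower at -1.3 ± 0.42 and the mucin MUC2 lower at -1.22 ± 0.37, each in 5 of 6 animals. RETNLB was not called without animal 70 (-0.91) or 75 (-1.05), nor MUC2 without animal 68 (-1.1), with quantile normalization (-0.99, adjusted p = 0.071), with normexp (-0.49) or with the authors' values (-0.66). KLK1 stood at 0.94 with normexp and was not called. Enteroendocrine genes gave 1 higher, 4 lower and 8 not called of 13, with 5 adjusted over the list alone and a median of -0.62 (adjusted p = 0.46). Neurotensin, NTS, was lower at -1.91 ± 0.48 in 5 of 6 animals and glucagon, GCG, at -1.86 ± 0.41, while the granin SCG5 was higher by 1.59 ± 0.25. The mean level of this list was 0.25 on the Peyer array of animal 71 and -1.06 to -0.66 on the others. Enteric neurons and glia gave 1 higher, 1 lower and 7 not called of 9, with 2 adjusted over the list alone and a median of -0.37 (adjusted p = 0.83). RET was higher by 1.35 ± 0.37, NCAM1 was lower at -1.04 ± 0.32 and UCHL1 stood at -0.73 ± 0.53, with this sign in 4 of 6 animals (adjusted p = 0.28). The call of NCAM1 was lost without animal 69 (-0.94), 70 (-0.98) or 73 (-0.99), and with median centring (-0.87), quantile normalization (-0.95), normexp (-0.7) and the authors' values (-0.67). That of RET was lost with normexp (0.63) and the authors' values (0.91). Slide medians of these 3 lists were -0.49, -0.1 and -0.66 for goblet and Paneth cells, -0.64, -0.31 and -0.76 for enteroendocrine cells, and -0.6, 0.02 and -0.36 for neurons and glia.

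Genes of plasma cells and IgA transport had a median of -0.14 and a mean of 0.09, and the test pointed up without passing (adjusted p = 0.81). Of 14 members 2 were higher, 1 lower and 11 not called, with 3 adjusted over the list alone. The gut chemokine CCL25 was lower at -1.15 ± 0.34, though not called with median centring (-0.97) or quantile normalization (-0.99), and CCL28 stood at -1.18 ± 0.83 in 5 of 6 animals (adjusted p = 0.26, 0.0055 with the 12 arrays compared alone and 0.0062 with slide as a block on them). Interferon response genes had a median of -0.05, a mean of 0.05 and an upward test (adjusted p = 0.76). By limma 0 of 26 were called, 0 when adjusted over the list alone, and 3 had an unadjusted p under 0.05. CXCL9 stood at 1.29 ± 0.53 (adjusted p = 0.053, and 0.045 with the animal as a replicate block), CXCL11 at 1.03 ± 0.54 in 5 of 6 animals and OAS1 at -0.99 ± 0.43. Without animal 71, CXCL9 (1.49) and OAS1 (-1.16) were called, and so was CXCL9 without animal 68 (1.38) and with median centring (1.47), normexp (1.24) and the authors' values (1.29). Slide medians were -0.36, 0.11 and -0.26 for the plasma cell list and -0.29, -0.09 and 0.34 for the interferon list.

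Of 9 adipose tissue genes 1 was higher, 2 lower and 6 not called, with 3 adjusted over the list alone and a median of -0.71 (adjusted p = 0.83). Perilipin, PLIN1, was higher by 2.68 ± 0.29 (well above background on 2 of 6 Jejunum arrays, and 0.99 with normexp), FABP4 was lower at -1.11 ± 0.33 in 5 of 6 animals and AQP7 stood at -1.1 ± 0.7 (adjusted p = 0.2). FABP4 was not called without animal 69 (-0.92) or 70 (-0.99), nor with median centring (-0.93), normexp (-0.85) or the authors' values (-0.91). Sex-linked genes had a median of -0.02, a mean of -0.22 and an upward test (adjusted p = 0.87). By limma 0 of 3 were called, 0 when adjusted over the list alone, and 2 had an unadjusted p under 0.05. DDX3Y stood at -0.02 ± 0.3, with either sign in 3 of 6 animals, and EIF1AY at 0.36 ± 0.12 and UTY at -0.99 ± 0.37, each in 5 of 6 animals. Of 18 housekeeping genes 0 were called by limma, 0 when adjusted over the list alone, and 7 had an unadjusted p under 0.05, with a median of -0.03 (adjusted p = 0.82). HPRT1 stood at 1 ± 0.18, SDHA at -0.87 ± 0.16 and B2M at -0.62 ± 0.19, and without animal 71 HPRT1 (1.15) and SDHA (-1.01) were called. HPRT1 was called without animal 69 (1.01) or 75 (1.02) too. Slide medians were -0.91, -0.32 and -0.63 for adipose genes, 0.33, 0.16 and -0.69 for sex-linked genes and -0.19, 0 and -0.05 for housekeeping genes.

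In all, 1431 genes were called between Peyer and Jejunum at an adjusted p under 0.05 and a change of at least 2-fold, 649 higher and 782 lower (45.4% higher). The median over all tested probes was -0.16. Median centring moved that median to 0.02 and the split to 866 higher and 478 lower (64.4% higher), and quantile normalization gave 731 and 578 (55.8%), normexp 490 and 336 (59.3%) and the authors' values 601 and 461 (56.6%), so the larger side depends on the scaling. With slide as a block 1438 genes were called. By limma treat 118 were called, 114 higher and 4 lower (96.6% higher). Slide 4 alone gave 115, of which 107 were higher and 8 lower, slide 6 alone 1519, and slide 5 alone 0 by limma, with 323 genes at an unadjusted p under 0.05, from 2 animals per slide. Without the Peyer array of animal 71, an alternative chosen after the data were seen, 2013 genes were called, 837 higher and 1176 lower, and 1420 of these were shared with the 1431.

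Between Spleen and Liver, genes of secreted plasma proteins, made by hepatocytes, were far lower in Spleen. The fibrinogen chains FGA, FGG and FGB differed by -13.49 ± 0.72 (limma adjusted p = 6.4e-14), -13.45 ± 0.81 and -12.84 ± 0.66, and were well above background on 2, 3 and 4 of 6 Spleen arrays. Transthyretin, TTR, differed by -11.91 ± 0.6, the acute phase protein ORM1 by -11.68 ± 0.7, LECT2 by -11.63 ± 0.39 and the carboxylesterases CES3 and CES1 by -11.31 ± 0.66 and -11.19 ± 0.59. Higher in Spleen were CXCL13 by 7.51 ± 0.76 (adjusted p = 6.2e-09), the smooth muscle genes ACTG2 by 6.44 ± 0.56 and CNN1 by 5.93 ± 0.55, MGC29506 by 6.3 ± 0.36 and the immunoglobulin light chain gene IGLL1 by 6.16 ± 0.45.

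All 36 measured plasma protein genes were lower in Spleen, and 36 adjusted over the list alone. The median was -10.72, or -10.66 with genes not well above background at their bound (adjusted p = 6.2e-23, and 0.067 with an estimated correlation). Slide medians were -10.51, -11.1 and -10.59 on slides 1, 2 and 3 (adjusted p = 3.3e-18 with slide as a block). The mean level of the list on the Spleen arrays was -0.96 in animal 68, -2 in animal 71 and -1.75 in animal 75, against -3.59, -3.88 and -2.89 in animals 69, 70 and 73, and it was 7.6 ± 0.11 in Liver. Genes of the urea cycle and amino acid breakdown had a median of -6.72 (adjusted p = 3.1e-11, and 0.021 with an estimated correlation), with 17 lower, 1 higher and 1 not called of 19, and 18 adjusted over the list alone. BHMT, a methyltransferase of methionine synthesis, differed by -13.01 ± 0.76, the tryptophan dioxygenase TDO2 by -12.27 ± 0.53 and the homogentisate dioxygenase HGD by -11.52 ± 0.47 (well above background on 2, 3 and 1 of 6 Spleen arrays). Genes of bile acid and xenobiotic metabolism had a median of -10.08, or -9.92 at the bounds (adjusted p = 1.9e-14, and 0.049 with an estimated correlation), with 24 lower, 0 higher and 2 not called of 26, and 24 adjusted over the list alone. The alcohol dehydrogenase ADH4 differed by -12.97 ± 0.42 and the flavin monooxygenase FMO1 by -12.7 ± 0.74 (1 and 4 of 6 Spleen arrays). Slide medians were -6.44, -6.98 and -6.76 for the urea cycle list and -10.6, -9.91 and -9.25 for the bile acid list (adjusted p = 4.4e-09 and 6.6e-12 with slide as a block).

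Neutrophil genes were higher in Spleen, with 10 higher, 0 lower and 6 not called of 16, and 10 adjusted over the list alone. Their median was 1.43 (adjusted p = 0.012, and 0.15 with an estimated correlation), with slide medians of 1.42, 1.58 and 1.67 (adjusted p = 0.0037 with slide as a block). The chemokine receptor CXCR2 was higher by 3.51 ± 0.17, PGLYRP1 by 3.4 ± 0.66 (well above background on 2 of 6 Liver arrays) and NCF4, a subunit of the phagocyte oxidase, by 2.77 ± 0.25. Genes of endothelium and sinusoids were lower, with 7 lower, 2 higher and 5 not called of 14, and 9 adjusted over the list alone. Their median was -1.07 (adjusted p = 0.048, and 0.43 with an estimated correlation), with slide medians of -0.83, -0.97 and -1.22 (adjusted p = 0.031 with slide as a block and 0.31 with slide as a random block). This call was lost without animal 70 (-1.02, adjusted p = 0.063) and without animal 75 (adjusted p = 0.061). The ficolin FCN2 differed by -5.05 ± 0.63, and the sinusoidal endothelial genes CLEC4G and LYVE1, a lectin and a hyaluronan receptor, by -3.2 ± 0.64 and -2.97 ± 0.27. Of the 2 probes of LYVE1 1 was called, and with only probes well above background on all arrays the gene stood at -0.98 and was not called.

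Of 5 measured pancreas genes, listed because the organ adjoins the spleen, 3 were higher, 2 lower and 0 not called, with 5 adjusted over the list alone, a median of 1.71 (adjusted p = 0.37) and slide medians of 2.1, 1.82 and 1.19. The elastase CELA1 was at least 29.8-fold higher in Spleen and the lipase CEL higher by 2.09 ± 0.29, while CELA2A differed by -1.99 ± 0.85 (adjusted p = 0.042). CELA2A stood at -1.84 in the Liver of animal 71, against 1.63 to 2.11 in the others, and leaving out any of the other 5 animals ended its call, with differences from -2.11 without animal 68 to -1.9 without animal 69 or 70. Immediate early and heat shock genes had a median of -0.12, a mean of 0.02 and a downward test (adjusted p = 0.89), with 3 higher, 3 lower and 11 not called of 17, and 6 adjusted over the list alone. HSP70.2 differed by -2.18 ± 0.52, and HSPA6 and IER3 were higher by 1.94 ± 0.63 and 1.73 ± 0.25. HSPA6 was not called with normexp (1.16, adjusted p = 0.074) or the authors' values (1.18, adjusted p = 0.069). The slide medians were -0.2, -0.37 and 0.11.

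Between Spleen and Liver 4222 genes were called, 2263 higher and 1959 lower in Spleen (53.6% higher), with a median of 0.15 over all tested probes. Median centring gave 2054 higher and 2144 lower (48.9%) and quantile normalization 2549 and 1843 (58%), so the larger side depends on the scaling. With slide as a block 4212 were called, and slides 1, 2 and 3 alone gave 3616, 3603 and 3883. Without the Spleen arrays of animals 68, 71 and 75, chosen after the data were seen, 4388 were called.

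Between Peyer and Spleen, the highest differences in Peyer included genes of the intestinal epithelium. Of 28 absorption genes 20 were higher and 1 lower (median 3.96, adjusted p = 0.042 with an estimated correlation), while the brush border list, with 16 of 19 higher and 0 lower, lost its call with an estimated correlation (adjusted p = 0.053), as did those of transcription factors and junctions (0.056), goblet and Paneth cells (0.059) and enteroendocrine cells (0.067). C19ORF77 was higher by 9.52 ± 0.54 (limma adjusted p = 7.4e-13), galectin 4, LGALS4, by 9.39 ± 0.49, the polymeric immunoglobulin receptor PIGR, which carries IgA across the epithelium, by 9.07 ± 0.39, the brush border peptidase ENPEP by 8.55 ± 0.29 and MTTP, which loads lipid onto lipoproteins, by 8.45 ± 0.35. On the Spleen array of animal 73 intestinal genes stood above the other Spleen arrays: LGALS4 at 1.45 against -2.92 to -2.62, C19ORF77 at 0.78 against -4.31 to -3.08 and MTTP at -1.19 against -4.11 to -3.71. Lower in Peyer were beta globin, HBB, at -8 ± 0.46 (adjusted p = 7.6e-13), the haemoglobin chaperone AHSP at -7.79 ± 0.4, the macrophage protein CD5L at -7.35 ± 0.29, KAZALD1 at -6.39 ± 0.26 and TNP2 at -5.95 ± 0.34.

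Macrophage genes of red pulp and liver were lower in Peyer, with 16 lower, 0 higher and 3 not called of 19, and 16 adjusted over the list alone. The median was -3.02, or -2.78 at the bounds (adjusted p = 5.6e-10, and 0.028 with an estimated correlation). The Kupffer cell lectin CLEC4F was at least 39.8-fold lower and CSF1R, the receptor of macrophage growth factor, differed by -4.61 ± 0.28. Erythroid genes gave 8 lower, 0 higher and 8 not called of 16, with 8 adjusted over the list alone and a median of -0.97 (adjusted p = 0.0018, and 0.15 with an estimated correlation). Dendritic cell and antigen presentation genes gave 9 lower, 0 higher and 6 not called of 15, with 9 adjusted over the list alone and a median of -1.06 (adjusted p = 7e-04, and 0.4 with an estimated correlation). The chemokine receptor XCR1 differed by -2.81 ± 0.21, the costimulator CD80 by -2.07 ± 0.28 and the invariant chain CD74 by -1.48 ± 0.21. On the Peyer array of animal 71 the mean level of this list was 1.3, against 2.32 to 2.61 on the others.

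Genes of NK and cytotoxic cells were lower in Peyer, with 12 lower, 2 higher and 4 not called of 18, and 14 adjusted over the list alone. Their median was -1.41 (adjusted p = 0.0021, and 0.36 with an estimated correlation). The transcription factor EOMES differed by -3.95 ± 0.27 and the receptor NCR1 by -3.81 ± 0.28 (well above background on 1 of 6 Peyer arrays), while granzyme A, GZMA, was higher by 3.8 ± 0.53. T cell genes had a median of -0.59 (adjusted p = 0.053, and 0.66 with an estimated correlation, 0.044 with the animal as a replicate block and 0.027 with the 12 arrays compared alone), with 6 lower, 0 higher and 12 not called of 18, and 5 adjusted over the list alone. SH2D1A differed by -2.01 ± 0.34, TRAT1 by -1.38 ± 0.22 and LEF1 by -1.24 ± 0.31, and LEF1 was not called without animal 71 (-0.9) or with median centring (-0.97). The list passed without animal 68, 70 or 73 (adjusted p = 0.039, 0.042 and 0.037). Homing genes had a median of -0.33, a mean of 0.22 and a downward test (adjusted p = 0.71), with 3 higher, 7 lower and 7 not called of 17, and 11 adjusted over the list alone. The chemokines CCL25 and CCL28 were higher by 7.81 ± 0.34 and 4.48 ± 0.83 (CCL28 well above background on 3 of 6 Spleen arrays), and the integrin ITGA4 differed by -2.43 ± 0.25. CCL25 stood at 0.37 on the Spleen array of animal 73, against -2.51 to -1.62 on the others, and the homing list at 0.46 on the Peyer array of animal 71, against 1.51 to 1.95.

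Platelet and megakaryocyte genes gave 1 higher, 1 lower and 9 not called of 11, with 3 adjusted over the list alone and a median of -0.4 (adjusted p = 0.77). GP1BB differed by -1.78 ± 0.28, P-selectin, SELP, was higher by 1.32 ± 0.15 and F13A1 stood at -1.27 ± 0.54 in 5 of 6 animals (adjusted p = 0.051, and 0.011 with the animal as a replicate block). F13A1 was called without animal 68 (-1.59) or 73 (-1.5) and stood at -0.82 without animal 71 (adjusted p = 0.13) and 0.06 with the authors' values (adjusted p = 0.95). Spleen stroma and patterning genes gave 3 lower, 0 higher and 5 not called of 8, with 3 adjusted over the list alone and a median of -0.59 (adjusted p = 0.15). The transcription factors WT1 and NR2F2 differed by -8.91 ± 0.56 and -2.41 ± 0.18 (WT1 well above background on 1 of 6 Peyer arrays), and TCF21 by -1.05 ± 0.27 in 5 of 6 animals. TCF21 was not called without animal 70 or 73 (-0.82 each), nor with median centring (-0.78), quantile normalization (-0.98) or normexp (-0.81).

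Between Peyer and Spleen 2742 genes were called, 1147 higher and 1595 lower in Peyer (41.8% higher), with a median of -0.18 over all tested probes. Median centring gave a median of 0.09 with 1568 higher and 1060 lower (59.7%), so the larger side depends on the scaling. The authors' values gave 783 higher and 413 lower (65.5%) of 1196. With the authors' values C19ORF77, LGALS4, CD5L, GZMA, CCL25 and CCL28 reversed, and ENPEP, SH2D1A, LEF1, EOMES, NCR1, CLEC4F, GP1BB, SELP, CD80 and NR2F2 lost their calls. Across the slide sets the authors' differences were smaller, and each slide held only 1 of the tissues compared. Slide could enter only as a random block (consensus correlation 0.038), giving 2733 genes here. Without the Spleen array of animal 73, chosen after the data were seen, 2782 were called.

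Between Jejunum and Liver, FABP2, the intestinal fatty acid binding protein, was at least 6130-fold higher in Jejunum (limma adjusted p = 4.6e-14), the peptidase subunits MEP1B and MEP1A at least 1970-fold and 969-fold, and sucrase-isomaltase, SI, at least 1590-fold. CCL25 was higher by 10.63 ± 0.34, C19ORF77 by 11.18 ± 0.54, LGALS4 by 9.59 ± 0.49, GUCA2A, which encodes guanylin, by 9.01 ± 0.35 and the sodium-glucose transporter SLC5A1 by 8.99 ± 0.33. Lower in Jejunum were the cytochrome CYP2E1 at -13.54 ± 0.62 (adjusted p = 4.3e-15), LECT2 at -12.35 ± 0.39, albumin, ALB, at -12.22 ± 0.58, hemopexin, HPX, at -12.16 ± 0.4 and ceruloplasmin, CP, at -12.14 ± 0.47.

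Of 19 brush border genes 17 were higher in Jejunum, 0 lower and 2 not called, with 17 adjusted over the list alone and a median of 6.85 (adjusted p = 1.4e-11, and 0.1 with an estimated correlation). Nutrient absorption genes gave 18 higher, 1 lower and 9 not called of 28, with 19 adjusted over the list alone and a median of 3.33, or 2.81 at the bounds (adjusted p = 5.4e-06, and 0.16 with an estimated correlation). The calcium binding protein S100G was higher by 12.87 ± 0.83 and the retinol binding protein RBP2 by 11.83 ± 0.69, and they were well above background on 4 and 2 of 6 Liver arrays. With only probes well above background on all arrays S100G stood at -0.09. Intestinal transcription factors and junction genes gave 13 higher, 1 lower and 5 not called of 19, with 14 adjusted over the list alone and a median of 1.7 (adjusted p = 0.00012, and 0.27 with an estimated correlation). KRT20 was higher by 11.95 ± 1.02, the transcription factor KLF5 by 8.35 ± 0.45 and the adhesion molecule EPCAM by 8 ± 0.52. KRT20 and KLF5 were well above background on 1 of 6 Liver arrays each. KRT20 stood at -0.36 in the Liver of animal 73 and -7.42 to -7.25 in the other Liver samples. With the authors' values the absorption list stood at -0.09 and the transcription factor list at -0.23, EPCAM reversed to -0.23, and C19ORF77, LGALS4, GUCA2A, SLC5A1, MEP1B, SI, MEP1A, FABP2, S100G, RBP2, KRT20 and KLF5 lost their calls, standing between 0.24 (KRT20) and 0.9 (C19ORF77).

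Genes of glucose and lipid metabolism of the liver were lower in Jejunum, with 20 lower, 0 higher and 5 not called of 25, and 20 adjusted over the list alone. Their median was -2.16 (adjusted p = 3.5e-09, and 0.0037 with an estimated correlation). Hepatic lipase, LIPC, differed by -7.84 ± 0.4 and the acyl-CoA synthetase ACSL1 by -6.25 ± 0.16. Liver transcription factors gave 5 lower, 1 higher and 3 not called of 9, with 6 adjusted over the list alone and a median of -1.1 (adjusted p = 0.091). The bile acid receptor NR1H4 differed by -3.7 ± 0.25 and PROX1 by -3.54 ± 0.23. Between Jejunum and Liver 3623 genes were called, 1884 higher and 1739 lower in Jejunum (52% higher, median 0.03 over all tested probes). The authors' values called 1254, of which 525 were higher and 729 lower (41.9%), and slide as a random block gave 3618.

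Peyer and Liver differed in 4383 genes, 2081 higher and 2302 lower in Peyer (47.5% higher, median -0.04), and Spleen and Jejunum in 3335 genes, 1663 higher and 1672 lower in Spleen (49.9%, median 0.16). Median centring gave a median of 0.12 between Peyer and Liver, with 2430 higher and 1992 lower (55%). Lists that had not passed in their own comparison passed here. T cell genes were higher in Peyer than in Liver in 15 of 18 members, with 0 lower and 3 not called, and had a median of 2.7 (adjusted p = 1.8e-05, and 0.28 with an estimated correlation). ICOS was higher by 4.21 ± 0.41, CCR7 by 3.6 ± 0.48 and CD3G by 3.6 ± 0.29. ICOS stood at -0.28 and CCR7 at -2.54 on the Peyer array of animal 71, against 1.7 to 2.5 and 0.66 to 1.74 on the others. They were higher in Spleen than in Jejunum in 13 of 18 members, with 0 lower and 5 not called, a median of 1.26 (adjusted p = 0.00026, and 0.35 with an estimated correlation) and CCR7 higher by 5.21 ± 0.48.

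Goblet and Paneth cell genes were higher in Peyer than in Liver, with 10 higher, 3 lower and 2 not called of 15, and a median of 6.1 (adjusted p = 0.0067, and 0.23 with an estimated correlation). The trypsin inhibitor SPINK1 was at least 4530-fold higher, the lectin ITLN2 at least 1290-fold and CLCA1 by 10.9 ± 0.55 (well above background on 1 of 6 Liver arrays). Against Jejunum they were lower in Spleen, with 9 lower, 1 higher and 5 not called and a median of -5.42 (adjusted p = 4.8e-05, and 0.077 with an estimated correlation). SPINK1 stood at 1.98 on the Spleen array of animal 73 and -7.99 to -6.52 on the others. Enteroendocrine genes gave 9 higher, 1 lower and 3 not called of 13 between Peyer and Liver (median 2.68, adjusted p = 0.002, and 0.22 with an estimated correlation), with glucagon, GCG, at least 72.7-fold and somatostatin, SST, at least 271-fold higher. Between Spleen and Jejunum 9 were lower, 1 higher and 3 not called (median -2.96, adjusted p = 0.00014, and 0.13 with an estimated correlation).

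Plasma cell and IgA transport genes were higher in Peyer than in Liver, with 10 higher, 2 lower and 2 not called of 14 (median 2.22, adjusted p = 0.003, and 0.067 with an estimated correlation), among them CCR9 by 4.63 ± 0.22 (well above background on 3 of 6 Liver arrays). Homing genes were higher in Peyer than in Liver in 13 of 17, with 0 lower and 4 not called (median 2.29, adjusted p = 0.0016, and 0.18 with an estimated correlation). They were higher in Spleen than in Jejunum in 12, with 4 lower and 1 not called (median 2.26, adjusted p = 0.028, 0.33 with an estimated correlation and 0.05 with slide as a random block). Liver transcription factors were lower in Peyer than in Liver in 6 of 9, with 1 higher and 2 not called (median -2.04, adjusted p = 0.013, and 0.33 with an estimated correlation), and FOXA1 differed by -2.73 ± 0.25. They were lower in Spleen than in Jejunum in 6, with 0 higher and 3 not called (median -5.38, adjusted p = 2.1e-05, and 0.11 with an estimated correlation), with NR5A2 at -6.36 ± 0.42 (well above background on 3 of 6 Spleen arrays). Adipose genes were lower in Spleen than in Jejunum in 5 of 9, with 1 higher and 3 not called (median -1.39, adjusted p = 0.04, 0.22 with an estimated correlation and 0.056 with slide as a random block), among them CIDEC at -8.11 ± 0.38 and AQP7 at least 8.13-fold lower. Over the 35 lists and 6 comparisons 107 of 210 tests passed, and 13 did with an estimated correlation. With the authors' values the goblet and Paneth (-0.12) and enteroendocrine lists (-0.36), SPINK1, CLCA1, SST and GCG reversed between Peyer and Liver and CCR9 (0.85) and ITLN2 (0.48) lost their calls, as did AQP7 (-0.52) between Spleen and Jejunum.

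Liver had the most genes that set it apart from all other tissues. With at least 4-fold over each other tissue, 615 genes were enriched in Liver (5.6% of those tested), 145 in Spleen (1.3%), 17 in Jejunum and 17 in Peyer (0.2% each). The Liver genes with the largest smallest difference were LECT2 at 11.63 ± 0.39 over the nearest tissue, HPX at 11.01 ± 0.4, prothrombin, F2, at 10.76 ± 0.41, antithrombin, SERPINC1, at 10.68 ± 0.28 and A1BG at 10.64 ± 0.5. In Spleen they were CHODL at 4.96 ± 0.28, CHN1 at 4.34 ± 0.24, the nuclear receptor PPARG at 3.72 ± 0.24, TLR8 at 3.61 ± 0.26 and CXCR2 at 3.51 ± 0.17. In Peyer they were GP2 at 4.68 ± 0.68, C3H2orf40 at 2.63 ± 0.63, BCL7A at 2.12 ± 0.26, SPIRE2 at 2.09 ± 0.52 and the B cell gene VPREB3 at 2.06 ± 0.4. The nearest tissue was Spleen for GP2, C3H2orf40, BCL7A and VPREB3. BCL7A lay above it in 6 animals, and the others in 5 of 6 each and below it in animal 71. FAXDC2 at 2.44 ± 0.34 over Peyer was the 1 Jejunum gene well above background on all 24 arrays. Without animal 71 the counts were 38 in Jejunum and 26 in Peyer, and without animal 69 Jejunum had 11.

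The series names the correlation of tissue profiles as an aim. Across 42650 probes the Peyer and Jejunum profiles of an animal correlated at 0.956 ± 0.021 (SD, n = 6), Peyer and Spleen at 0.867 ± 0.032, Spleen and Jejunum at 0.823 ± 0.015, Jejunum and Liver at 0.778 ± 0.005, Spleen and Liver at 0.766 ± 0.012 and Peyer and Liver at 0.763 ± 0.009. These values are across probes, and probes are not independent replicates. Of the 15 differences between tissue pairs, 13 reached an exact two-sided sign-flip permutation p = 0.031 (adjusted p = 0.036), the smallest that 64 sign flips of 6 animals allow. Peyer lay closer to Spleen than Jejunum did in 6 of 6 animals, by 0.045 ± 0.021 (SD, exact permutation p = 0.031). Spleen with Liver did not separate from Jejunum with Liver (-0.012 ± 0.011, exact permutation p = 0.094, adjusted p = 0.1) or from Peyer with Liver (0.003 ± 0.013, exact permutation p = 0.59). Tissues on shared and on different slides enter these pairs unequally.

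Some genes followed the animal in all tissues. With animal as a term beside tissue, 454 genes had an animal effect by the limma F-test, and 2021 had an unadjusted p under 0.05. The count was 282 with the authors' values and 131 to 166 without any 1 tissue. The leading genes were NGLY1, a deglycosylating enzyme of the cytosol (F = 112, adjusted p = 2.9e-09), the pseudouridine synthase PUSL1 (F = 94.6), the histocompatibility gene HLA-E (F = 79.8), TOMM5 of the mitochondrial import channel (F = 68.1) and POLR3F, a subunit of RNA polymerase III (F = 67.2). NGLY1 deviated from the tissue means by 1.32 in animal 69 and 1.4 in animal 73 and by -0.95 to -0.41 in the other 4. HLA-E deviated by -3.63 in animal 69 and -2.84 in animal 70 and by 0.77 to 2.6 in the other 4. The sex-linked genes DDX3Y, EIF1AY and UTY had no animal effect past the test (adjusted p = 0.57, 0.51 and 0.43). With slide as a fixed term before the animal 259 genes were called. Animals are nested in pairs within slides, so part of an animal effect and a slide effect cannot be told apart, although each animal lies on 2 slides.

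**Figure D4:**
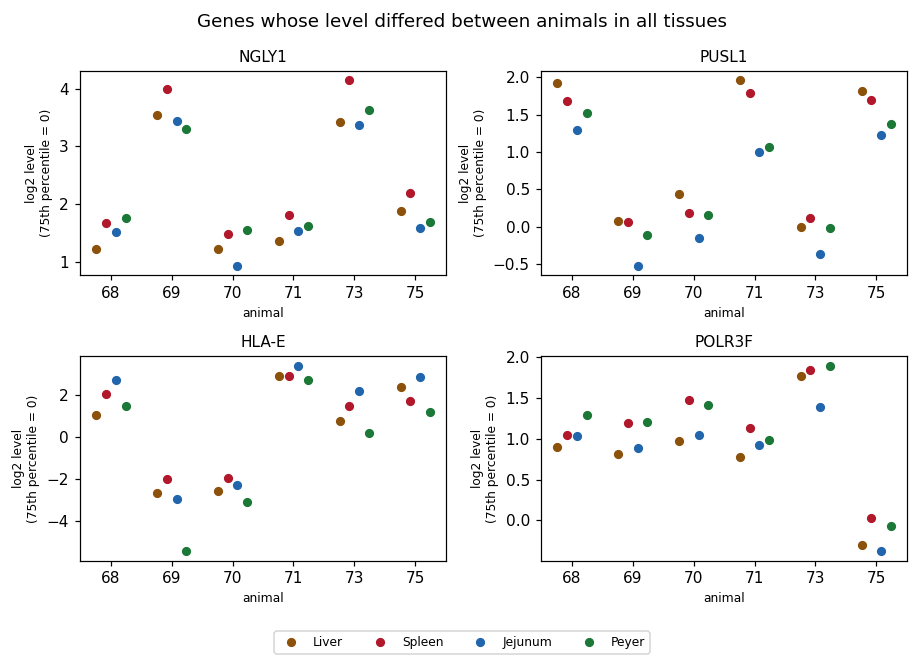
Log2 levels of NGLY1, PUSL1, HLA-E and POLR3F by animal, with 1 point per tissue in each of the 6 animals.

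Deviations of an animal from the tissue mean were shared between tissues. The mean product of standardised deviations in matched animals was 0.192 for Peyer and Jejunum, 0.158 for Spleen and Liver, 0.155 for Peyer and Spleen, 0.121 for Jejunum and Liver, 0.109 for Peyer and Liver and 0.014 for Spleen and Jejunum. Against all 720 pairings of animals, the one-sided exact permutation p was, in that order, 0.0014, 0.0056, 0.0014, 0.0014, 0.0028 and 0.41 (adjusted p = 0.0028, 0.0067, 0.0028, 0.0028, 0.0042 and 0.41), with 0.0014 the smallest it can be. Among the 8 pairings that only exchange animals of the same slide, the matched one ranked highest for 4 of the 6 tissue pairs, with 2 pairings as high for Peyer and Liver and 6 for Spleen and Jejunum.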

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

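Of the tests weighed in this part, the rank correlations of Spleen arrays with liver and jejunum were chosen before their result was seen, and those of the Peyer array of animal 71, of genes far below the liver or jejunum and of the background were chosen after it. Within each tissue, an array stood apart where its gap to the nearest of the other 5 was too large a part of the range of all 6 by Dixon's test at the 95% level. Among 68 groups of list levels 10 stood apart, among 329 groups of gene levels 63, and among 8 groups of array measures and 10 of profile correlations 0. Chance gives about 5% of groups, or 1 in 20. Of the arrays, the Peyer array of animal 71 accounts for 38, the Liver array of animal 73 for 8 and the Spleen array of animal 73 for 6. Values below are log2 levels relative to the array's 75th percentile, with the range of the other 5 animals of the tissue.

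On the Peyer array of animal 71 the lists of B cells (-0.95, others 1.51 to 1.69), germinal centre (-0.54, others 1.44 to 1.75), cell cycle (-0.55, others 0.8 to 1.1), follicle-associated epithelium and M cells (-0.52, others 0.71 to 1.38), homing (0.46, others 1.51 to 1.95) and dendritic cells (1.3, others 2.32 to 2.61) were low, and enteroendocrine cells were high (0.25, others -1.06 to -0.66). B cell and germinal centre genes were low there: CR2 at -3.29 (others 1.3 to 2.04), MS4A1 at -1.19 (1.94 to 2.48), CD79B at 0.68 (3.93 to 4.4), FCRLA at -1.5 (1.93 to 2.31), VPREB3 at 2.6 (4.72 to 5.57), ELL3 at 0.85 (4.16 to 4.37), CXCL13 at -0.06 (5.1 to 5.69) and BACH2 at -1.56 (1.61 to 2.47). So were the T cell genes SH2D1A at -3.93 (-2.16 to -1.56), ICOS at -0.28 (1.7 to 2.5) and CCR7 at -2.54 (0.66 to 1.74), the cell cycle genes RRM2 at 1.21 (2.97 to 3.47), TPX2 at 1.35 (2.91 to 3.28) and MCM3 at -1.59 (0.04 to 0.33), and the genes GP2 at -1.55 (2.42 to 4.75) and PGLYRP1 at -7.91 (-3.49 to -2.45). Further low values were FABP6 at 2.51 (5.69 to 6.9), KLK1 at -4.19 (-2.65 to -1.9), SCG5 at -1.28 (0.42 to 0.82), TLR10 at -2.3 (-0.59 to 0.02), TLR2 at -2.36 (-0.43 to 0.44), LTB at 1.47 (4.77 to 5.11), IL6 at -5.72 (-3.18 to -2.41), IL16 at 1.55 (2.97 to 3.5), PLIN1 at -4.71 (-3.11 to -2.32), HPRT1 at 0.68 (1.63 to 2.07), F13A1 at -1.75 (1.24 to 1.93), C3H2orf40 at 1.38 (5.23 to 5.58) and BCL7A at 1.21 (2.94 to 3.47). LGALS4 at 8.23 (7.02 to 7.47) and SST at 4.56 (2.52 to 3.16) were high.

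The Peyer array of animal 71 thus lies between the other Peyer arrays and the Jejunum. A swap with the Jejunum sample of the same animal is argued against by that Jejunum array, whose median position on the B cell list was -0.002 on a linear scale from 0, the other Jejunum arrays, to 1, the other Peyer arrays, and the same RNA on both arrays by a median B cell difference of 1.52 log2 between them. A smaller share of patch tissue is a candidate explanation. Between the animal's Jejunum and the other Peyer arrays, 15 B cell genes had a median position of 0.08 and 9 germinal centre genes 0.08. It was 0.08 for the other 813 genes higher in the other Peyer arrays, immune genes included. For 25 T cell, homing, follicle-associated epithelium and dendritic cell genes it was 0.05. The 1176 genes lower in the other Peyer arrays had a median position of 0.23 (quartiles 0.08 and 0.43). Whether the animal had a smaller patch or the piece taken held less of it stays open, and no biological explanation was tested.

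On the Spleen array of animal 73 intestinal genes were high: SPINK1 at 1.98 (others -7.99 to -6.52), C19ORF77 at 0.78 (-4.31 to -3.08), LGALS4 at 1.45 (-2.92 to -2.62), MTTP at -1.19 (-4.11 to -3.71) and CCL25 at 0.37 (-2.51 to -1.62), as was HSPA6 at -1.41 (-1.99 to -1.77). On that of animal 75 CLEC4G was at 0.77 (2.67 to 3.45), CEL at -3.53 (-2.31 to -1.74) and TNP2 at -0.84 (0.72 to 1.46), and on that of animal 71 CELA2A was at -3.5 (-0.79 to 0.7).

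Some Spleen arrays show transcripts of other organs, liver on those of animals 68, 71 and 75, and intestine and, to a lesser extent, liver on that of animal 73. For genes well above background, a higher background on the arrays of animals 68, 71 and 75 is argued against: 22 plasma protein genes well above background on those of animals 69 and 70 rose by 1.47, 1.06 and 1.27, and other genes of the same level by 0.01, 0.13 and 0.02, a ratio of 0.12 at most. On that of animal 73 they rose by 0.5 and the others by -0.03. The brush border list rose by 0.16, -0.07 and 0.01 and the plasma protein list by 2.48, 1.35 and 1.74 (ratio 0.06 at most), with 0.36 and 0.56 for animal 73. Near the background, 72 genes at background on all Liver and Spleen arrays rose by 0.91, 1.41 and 0.32 and the other 14 plasma protein genes by 4.47, 2.55 and 3.13. Ratios were 0.2, 0.55 and 0.1, with 14, 9 and 14 of the 14 above the upper quartile of the 72. Picking the 72 as at background on these arrays too limits their rise, so a higher background stays open there. Liver RNA or tissue in these samples may account for the liver transcripts, but the tests leave it open: over 615 genes enriched in Liver the rank correlation of the excess with the liver level was 0.3 for animal 68, 0.083 for animal 71 and 0.119 for animal 75, and of 109 genes at least 1000-fold below the liver 83.5%, 73.4% and 57.8% were raised by over 1 log2, with 34.9% for animal 73. Jejunum RNA or tissue in the sample of animal 73 stays open as well, with a rank correlation of 0.324 over 411 genes and 92.9% of genes far below the jejunum raised, against 64.3% for animal 71. The rank correlation of 0.5 set in advance was reached in neither case, and no biological explanation was tested.

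On the Liver array of animal 73 KRT20 stood at -0.36 (others -7.42 to -7.25), and MEP1B at -6.59 (-7.37 to -7.18), SI at -6.05 (-7.23 to -7.1), MEP1A at -5.54 (-7.13 to -6.96), FABP2 at -6.38 (-7.11 to -6.88), ITLN2 at -6.39 (-7.12 to -6.91) and GCG at -6.65 (-7.39 to -7.25) were higher than on the others at levels near the background, while CCR7 was lower at -4.38 (-3.13 to -2.58). On the Liver array of animal 75 CXCL13 stood at -2.39 (-4.08 to -3.51) and IER3 at -2.17 (-3.94 to -3.39), and on that of animal 71 CELA2A at -1.84 (1.63 to 2.11).

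Among the Jejunum arrays, goblet and Paneth cell genes were high in animal 70 (2.91, others 2.01 to 2.27), smooth muscle genes low in animal 71 (3.04, others 3.88 to 4.33) and B cell genes high in animal 75 (-2.36, others -2.72 to -2.59). In animal 71 SYNM was low at 3.01 (4.21 to 4.78) and FABP2 high at 8.01 (7.44 to 7.62). In animal 73 CCND1 was high at 7.12 (5.62 to 6.08) and MS4A1 low at -6.19 (-5.31 to -5.11). In animal 75 OAS1 stood at 3.91 (4.84 to 5.39), ALB at -3.5 (-2.4 to -1.76) and POLR3F at -0.38 (0.89 to 1.39), all low. Among the other Peyer arrays, CCND1 was at -5.71 in animal 69 (2.39 to 5.14) and CD3G at 2.18 in animal 70 (1.46 to 1.69). In animal 75 XCR1 was at -1.82 (-1.27 to -1.01) and WT1 at -4.76 (-9.1 to -7.67).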

How the results depend on the processing

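Of the tests in this part, those of quantile normalization alone and of the columns of the authors' table, and the alternatives without the Peyer array of animal 71, without Spleen arrays and without slide 6, were chosen after the result was seen. Among counts and correlations 281 values stayed close to the reported one and 78 moved. Among list results 4960 kept direction and side of the threshold, 190 lost and 139 gained a call and 19 reversed, and among named genes 3520 kept both, 179 lost and 43 gained a call and 15 reversed. The animal as a block changed the call of no named gene or list other than those given with it in the report, besides NK and cytotoxic genes between Jejunum and Liver (0.92, adjusted p = 0.046; without the block adjusted p = 0.6 with an estimated correlation). Below, the cause was not tested unless the way an alternative is built shows it.

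With the authors' values 1196 genes were called between Peyer and Spleen, 1254 between Jejunum and Liver, 2135 between Peyer and Liver and 2137 between Spleen and Jejunum. Enriched genes numbered 268 in Liver, 13 in Spleen, 1 in Peyer and 0 in Jejunum by limma (0 at an unadjusted p under 0.05), and 282 genes had an animal effect. Profile correlations were 0.808 for Spleen and Liver, 0.95 for Peyer and Spleen, 0.949 for Jejunum and Liver, 0.916 for Peyer and Liver and 0.922 for Spleen and Jejunum. Between Peyer and Spleen plasma proteins (3.86), brush border (-0.27) and enteroendocrine genes (-0.14) reversed, as did C19ORF77 (-0.71), LGALS4 (-0.16), CD5L (1.02), GZMA (-1.09), CCL25 (-1.18) and CCL28 (-0.08). Between Jejunum and Liver absorption (-0.09), transcription factor and junction (-0.23), macrophage (0.35) and erythroid lists (0.2) reversed, as did EPCAM (-0.23). Goblet and Paneth (median 0.1) and enteroendocrine lists (0.09) reversed in test direction alone. Between Peyer and Liver brush border (-0.73), absorption (-0.96), goblet and Paneth (-0.12), enteroendocrine (-0.36), transcription factor and junction (-1.34), macrophage (0.64), erythroid (0.41), neutrophil (0.79) and housekeeping lists (0.41) reversed, with SPINK1 (-0.12), CLCA1 (-0.22), SST (-0.66), GCG (-1.03) and NTS (-0.86), and ITLN2 (0.43) between Spleen and Jejunum.

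In the authors' table, differences between tissues on different slides are smaller than in the scanner signals. FABP2, chosen here after its values were seen, averaged 10.95 in Liver and 11.72 in Jejunum there, against 2.33 and 17.24 in quantile-normalized scanner signals. Columns belonging to other arrays are argued against, since 24 of 24 columns had their highest rank correlation with their own array (0.949 to 0.979), and so is quantile normalization alone, which left a share of 0.411 of the variance between the slide sets, against 0.007 in the table. Removal of a mean per slide from each probe may account for it: the authors' difference of Jejunum and Liver correlated at 0.988 with that of scanner signals treated so. Such a step takes away the part of a tissue difference that lies between slides, and no biological explanation was tested.

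With normexp 826 genes were called between Peyer and Jejunum and 1824 between Peyer and Spleen, 3 were enriched in Jejunum and 10 in Peyer, and the housekeeping list between Peyer and Liver reversed (0.61, adjusted p = 0.045). Profile correlations were then 0.796 for Spleen and Liver, 0.899 for Peyer and Spleen, 0.814 for Jejunum and Liver, 0.803 for Peyer and Liver and 0.858 for Spleen and Jejunum. Genes enriched in Jejunum numbered 6 with median centring, 9 with quantile normalization and 32 with array weights. Leaving out 1 animal gave 11 (without 69) to 38 (without 71) in Jejunum and 14 (without 68, 73 or 75) to 26 (without 71) in Peyer. Without the Peyer array of animal 71 Jejunum had 37, and without slide 6, with fewer arrays, Peyer had 10.

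Signal over background limits the rest. With only probes well above background on all arrays, and so fewer genes, 929 were called between Peyer and Jejunum and 387, 87, 1 and 6 were enriched in Liver, Spleen, Jejunum and Peyer. S100G, represented by another probe there, stood at -0.09 between Jejunum and Liver. Profile correlations in the order above were 0.809, 0.912, 0.852, 0.827 and 0.877, and 0.865, 0.924, 0.875, 0.866 and 0.902 with no filter. By Spearman's rho Spleen and Liver had 0.786, Jejunum and Liver 0.803 and Peyer and Liver 0.787. With 1 value per named gene Jejunum and Liver had 0.766 and Peyer and Liver 0.752.

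Thresholds act by construction. By adjusted p alone 4853 genes were called between Peyer and Jejunum, 7644 between Spleen and Liver, 6064 between Peyer and Spleen, 6968 between Jejunum and Liver, 7984 between Peyer and Liver and 6771 between Spleen and Jejunum, with 2149, 1595, 876 and 307 enriched in Liver, Spleen, Jejunum and Peyer. By limma treat 118 were called between Peyer and Jejunum, 1259 between Peyer and Spleen, 2264 between Jejunum and Liver, 2735 between Peyer and Liver and 1978 between Spleen and Jejunum, with 26 enriched in Spleen, 1 in Peyer and 0 in Jejunum (0 at an unadjusted p under 0.05). Of the 210 list tests 13 passed with an estimated correlation and 161 with fry.

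From 4 arrays per slide, Peyer and Jejunum differed in 115 genes on slide 4 and 0 on slide 5 by limma (323 at an unadjusted p under 0.05), and SYNM stood at 0.08 on slide 6. With slide entered before the animal 259 genes had an animal effect, and with fewer arrays 161 without Liver, 158 without Spleen, 131 without Jejunum and 166 without Peyer.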

Other observations

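Of the tests in this part, that of bile acid uptake genes was chosen after the result was seen. Lists were tested outside their own comparison too. Between Peyer and Jejunum, lists of absorbing epithelium were lower in Peyer, in part of their members. Of 19 brush border genes 11 were lower, 0 higher and 8 not called (median -1.14, adjusted p = 4.8e-05, and 0.31 with an estimated correlation), of 28 absorption genes 12 were lower and 1 higher (median -1, adjusted p = 0.0013, and 0.31 with an estimated correlation) and of 19 transcription factor and junction genes 5 were lower and 14 not called (median -0.95, adjusted p = 0.0016, and 0.36 with an estimated correlation). Some immune lists beyond B cells were higher: homing genes in 10 of 17 members with 1 lower (median 1.04, adjusted p = 0.00023, and 0.12 with an estimated correlation), dendritic cell genes in 7 of 15 (median 0.77, adjusted p = 1.1e-06, and 0.23 with an estimated correlation) and T cell genes in 5 of 18 (median 0.73, adjusted p = 5.2e-05, and 0.31 with an estimated correlation). Neutrophil (0.49, adjusted p = 0.11), macrophage (0.02, adjusted p = 0.26) and NK and cytotoxic genes (-0.45, adjusted p = 0.63) did not pass.

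FABP6, which binds bile acids in the cells of the distal small intestine, averaged 5.9 in Peyer, -0.82 in Jejunum, 2.54 in Spleen and -4.82 in Liver. A candidate explanation is that the Peyer sections came from a more distal part of the intestine than the Jejunum sections. The other measured genes of ileal bile acid uptake, chosen after seeing FABP6, had a median difference of -0.54 between Peyer and Jejunum. SLC10A2 stood at 0.11 ± 0.21 and SLC51B at -1.19 ± 0.78 (SE, n = 6, adjusted p = 0.69 and 0.22). With only 2 such genes, SLC10A2 low in all 4 tissues (-3.79 to -3.24) and SLC51B variable, the question stays open.

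Genes that follow the animal may do so because a sequence variant lies under the probe. Of 221 such genes with another tested probe, 143 (64.7%) had a probe whose animal means correlated at 0.8 or more with those of the representative probe, against 50.5% of 442 other genes, and 109 had another probe with an animal effect. The share lies between the bounds set before the result was seen, so a variant under the probe and a difference in expression cannot be told apart for these genes as a set. In 10 genes the animals fell into groups more than 1 log2 apart in every tissue. The widest gaps were 3.26 for HLA-E and 1.54 for NGLY1, and, chosen after their values were seen, 2.42 for CELA2A, 1.96 for AMOTL2 and 1.67 for NPM2.

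Other divisions of the same arrays were fitted to see whether chance gives as many calls. For each comparison 100 splits of the 12 arrays into 6 and 6, the real one included, gave 1 split with as many genes. This was the real one, so chance is argued against. The real counts and the highest others were 1431 and 1399 for Peyer and Jejunum, 4222 and 2925 for Spleen and Liver, 2742 and 1789 for Peyer and Spleen, 3623 and 2386 for Jejunum and Liver, 4383 and 3216 for Peyer and Liver and 3335 and 2156 for Spleen and Jejunum. Among the 32 splits that part all 6 pairs, as the real one does, the highest others were 1188 for Peyer and Jejunum, 2866 for Spleen and Liver and 3106 for Peyer and Liver, and the same as above for the rest. The split with 1399 genes exchanges the Peyer array of animal 71 with the Jejunum array of animal 68, and so keeps most of the real division. Of 100 regroupings of the 24 arrays, 1 gave as many enriched genes in Liver (615, highest other 493) and Spleen (145, highest other 37). In Peyer 1 did (17, highest other 0) and in Jejunum 2 (17, highest other 77). Chance is argued against for Liver, Spleen and Peyer and stays open for Jejunum, where another gave more. The 77 came with animal 71's Peyer array in place of its Jejunum array. For the animal effect 1 regrouping of the animals gave as many genes (454, highest other 2), so chance is argued against there too. For the lists 2 of 100 regroupings, the real one among them, gave as many passing tests (107, highest other 112). That share is under 5%, but the regrouping with 112 left only 7 of the 24 arrays in their own tissue, so the number of passing lists alone is not taken to exclude chance.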
